A study of Caenorhabditis elegans with 2 samples.

How the data were processed

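Anti-GFP ChIP-seq was done on 2 biological replicates of C. elegans early embryos aged 2 hours, collected by egg bleaching, from a line expressing CEH-13 with a GFP-containing tag, per the labels. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. Per the deposited file descriptions, the authors called peaks on each replicate and on the pooled alignments of both, with the same control alignment each time, and derived an IDR-thresholded list from those 3 lists. The peak caller, the aligner and the IDR threshold are not given in the sources used here, and the control reads were not analysed here. The build is ce11, per the labels. The deposited signal of each peak is a score whose scale is not stated, and it was used only to rank and describe peaks within a list. The deposited lists also give −log10 of a q-value for each peak; in the IDR list 369 of 512 peaks were tied at the highest value, 2.87, so the signal score was used for ranks. Each of the 3 other lists held exactly 30000 peaks. In these lists 1380 peaks of replicate 1, 1082 of replicate 2 and 1146 of the pooled list had a q-value under 0.05, so most listed peaks are weak. The 512 IDR peaks are the 512 peaks of highest signal in the pooled list.

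Positions were matched to the WBcel235 reference sequence, the same assembly as ce11, with the annotation of Ensembl release 115. No peak ended beyond a chromosome end, and 99.9% of 31805 annotated start codons read ATG in the sequence. tRNA product names and tRNA pseudogenes came from the RefSeq annotation. Overlapping IDR peaks were merged into 493 regions, each with the summit and signal of its strongest peak. Coordinates are 1-based. Peak positions lay on the 6 nuclear chromosomes, which hold 19973 protein-coding genes.

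Replicates were compared over the 493 strongest peaks of each list, taken without merging, with an overlap of at least 1 bp, and by the rank correlation of signal across the regions. Random placement of peaks (100 draws) gave the overlap by chance. Summits were put in the first class that applied of promoter window (1000 bp upstream to 500 bp downstream of a protein-coding 5′ end), exon, intron, gene without a protein product, and intergenic, and each class was compared with the share of the genome by a two-sided exact binomial test. Chromosomes were compared with their length by the same test. Genes with a summit in their promoter window were counted over 21 gene lists and over 175 name families of at least 10 members, by two-sided Fisher exact tests against all other protein-coding genes. The names ceh-44 and elt-5 in the lists matched no gene. Motifs and 6-mers were counted on both strands in windows of 100 bp to each side of the summit, against 10 control windows per region. Controls were matched on chromosome, promoter state and GC content (within 2 percentage points) and kept at least 1 kb from any region; the GC content was 45.4% in the windows and 44.6% in the controls, against 35.4% of the genome. Tests on annotation classes, small RNA classes, tRNA genes, tRNA products, chromosomes, gene lists, name families, motifs and 6-mers were adjusted within each family by Benjamini-Hochberg at 0.05, and a p not called adjusted is raw. p-values describe counts of regions or genes, and since neighbouring genes can share a region they are approximate. With 1 group there was no comparison between groups.

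The lists, motifs, tests and most alternatives were fixed before the data were examined. Genes named in the text are the protein-coding genes in whose window the 20 strongest regions fall, every Hox or Hox cofactor gene with a region, the 3 members of highest signal in each other list, and ceh-13 and unc-119 in any case. Small RNA genes fall outside that rule and were chosen after their values were seen, as were rpl-35, rps-19, rps-26, his-59 and srrt-1, named to complete their counts. Alternatives were each replicate alone, the pooled list, the stronger 246 regions, unmerged peaks, other promoter windows and assignments, other motif windows and controls, and the regions without those at small RNA genes. Random draws and permutations used fixed seeds.

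The tests were tested on simulated data. With 329 genes drawn at random from 19973, at least 1 of the gene lists passed in 3% of 100 draws. These draws took each gene independently, while in the data 84 regions lay in the windows of 2 or more genes, so the rate of false calls in the data can differ. With ribosomal protein genes made 5 times as likely to be drawn, that list passed in 49% of draws, so effects of that size in a list of 76 genes are missed about as often as found. With random positions in place of the 493 regions, a motif passed in 5% of 20 draws, and the composite site was recovered in 95% of draws when written into 10% of windows. The positions were drawn evenly over the genome, of GC content 35.4%. The summit windows had 45.4% and seldom lay in exons, so both rates can differ in the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.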

Results

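The data are peak lists from chromatin immunoprecipitation and sequencing (ChIP-seq) of early Caenorhabditis elegans embryos of strain OP756. The worms carried a transgene of ceh-13 fused to an EGFP-containing tag together with a functional unc-119 gene, and an anti-GFP antibody was used. ceh-13 encodes the labial-type Hox protein of the worm, a homeodomain transcription factor. The single group held 2 biological replicates of embryos aged 2 hours, and the question was where in the genome the tagged protein is found. Each replicate list and the list from the pooled replicates held 30000 peaks. The list of peaks that passed the authors' irreproducible discovery rate (IDR) step held 512. Overlapping peaks of that list were merged into 493 regions, which covered 0.189% of the nuclear genome and are called regions from here on. The lists give no read numbers, so the depth is unknown, and 95% intervals on shares (Wilson) cover the counting of regions or genes only.

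The replicates shared most of their strongest peaks. Of the 493 strongest peaks of replicate 1, taken without merging, 329 (66.7%, 95% interval 62.5 to 70.7) overlapped the 493 strongest of replicate 2 by at least 1 bp. Random placement within chromosomes gave 0.402% on average over 100 draws, and random draws from the list of replicate 1 gave 1.97%. Of the 493 regions, 319 were among the strongest of both replicates, and 30 were among the strongest of neither. Across the 493 regions, which are not independent replicates, the signals in the 2 replicate lists had a Spearman rho of 0.709 (95% interval 0.661 to 0.752). Both lists were called against the same control alignment, so part of this likeness can come from that control. The regions were selected by the IDR step, which rests on agreement of the replicates. The count of 319 regions and the rho therefore cannot test that agreement.

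The strongest regions lay at genes for small structural RNAs. Of the 493 regions, 192 (38.9%) had their summit within 500 bp of a tRNA gene, where 0.632% of the genome lies (two-sided exact binomial test, adjusted p = 9.34e-282 over 5 tests). Near snoRNA genes, whose products guide the modification of other RNAs, lay 60 regions (12.2%), against 0.377% of the genome (exact binomial test, adjusted p = 1.30e-68). At the genes of spliceosomal and related snRNAs lay 12 regions (2.43%, against 0.117%, exact binomial test, adjusted p = 1.82e-12), and none lay at an rRNA gene. Together 263 regions (53.3%) were at such genes, with a region near more than 1 class counted once, against 1.14% of the genome weighted by chromosome. These gene classes were examined in detail only after their counts had been seen, and the genes named in this paragraph and the next were chosen after their values were seen. Among the 20 strongest regions, 15 lay at small RNA genes. The region of rank 2 (V, 12303418 to 12303867, signal 707) covered the snoRNA genes C51F7.4 and C51F7.3, rank 3 (II, 11960631 to 11961040, signal 687) lay at the snoRNA gene W03C9.9, and rank 6 (X, 13665396 to 13665756, signal 530) lay at the tRNA-Leu gene C04A11.t1.

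Counted by gene, 214 of 612 tRNA genes (35%, 95% interval 31.3 to 38.8) had a region, as had 62 of 346 snoRNA genes (17.9%) and 14 of 129 snRNA genes (10.9%). Only 3 of 209 tRNA pseudogenes (1.44%, 95% interval 0.489 to 4.13) had a region, fewer than of the tRNA genes (two-sided Fisher exact test, adjusted p = 6.24e-28 over 4 comparisons of tRNA genes). None of the 20 annotated rRNA genes had a region, which allows a share of up to 16.1% if they are counted as independent genes. Over tRNA genes the summits sat inside the gene in 65.6% of 192 regions, at a median of 33.5 bp from its 5′ end, whereas at snoRNA genes the median summit lay upstream, at -44 bp. None of the 20 tRNA product classes passed a two-sided Fisher exact test against the other tRNA genes after Benjamini-Hochberg adjustment, nor did the 5 tRNA genes without a named product; the lowest adjusted p was 0.285, for tRNA-Ala (18 of 34 genes) and tRNA-Gln (4 of 27 genes), whose raw p were 0.0272 and 0.0237. The median signal was 163 at small RNA genes and 112 elsewhere (two-sided permutation test, p = 2e-05, the smallest that 100000 permutations can give).

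**Figure D1:**
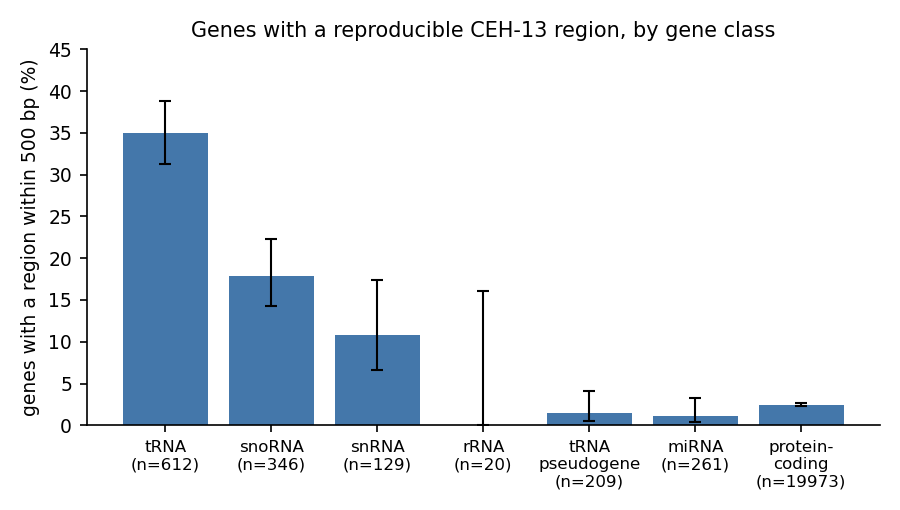
Share of genes in each annotated class (x axis, with the number of genes) that had a region summit inside the gene or within 500 bp of it (y axis, percent). Bars are shares with 95% Wilson intervals, and tRNA genes stand at 35% against 1.44% for tRNA pseudogenes.

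The share at small RNA genes fell with signal rank. It was 76% among the 100 strongest merged pooled peaks, 64% at ranks 101 to 250, 37.4% at ranks 251 to 493 and 11.2% at ranks 494 to 1000. Beyond rank 5000 it was 1.13%, close to the 1.09% of the genome.

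**Figure D2:**
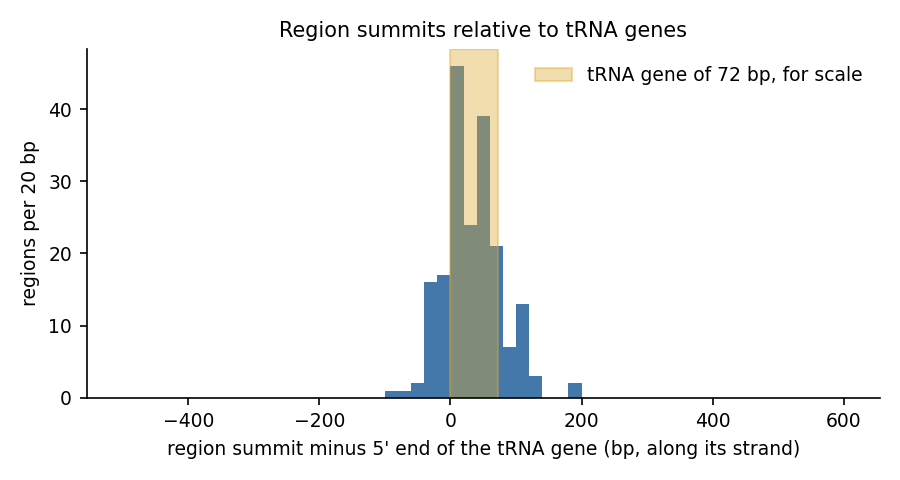
Number of region summits per 20 bp (y axis) by distance from the 5′ end of the nearest tRNA gene along its strand (x axis, bp), for the 192 regions at tRNA genes. The shaded band marks a gene of 72 bp, and 65.6% of the summits lay inside their gene.

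Protein-coding promoters came next. The summit fell within 1000 bp upstream to 500 bp downstream of a protein-coding 5′ end in 237 regions (48.1%), against 25.8% of the genome (two-sided exact binomial test, adjusted p = 7.49e-26 over 5 annotation classes). Protein-coding exons held 12 regions (2.43% against 20.8%, exact test, adjusted p = 3.26e-33) and introns 132 (26.8% against 28.4%, adjusted p = 0.454). Genes without a protein product, which include the small RNA genes, held 55 (11.2% against 3.2%, exact test, adjusted p = 3.84e-15), and intergenic sequence 57 (11.6% against 21.8%, adjusted p = 5.35e-09). The promoter share was 71.3% (164 of 230) among regions away from small RNA genes and 27.8% (73 of 263) among those at them, and the difference passed a two-sided Fisher exact test (p = 2.11e-22). Against the genome, the share at small RNA genes did not pass (25.39% of the genome, exact binomial test, p = 0.395).

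In all, 329 of 19973 protein-coding genes (1.65%) had a region in this promoter window. The strongest region of the whole list (III, 8043744 to 8044121, signal 720) had its summit at -537 bp from the 5′ end of K12H4.5 (WBGene00019680), away from small RNA genes. A region of rank 12 (III, 4568629 to 4568881, signal 418) lay between the divergent genes idhg-1, an isocitrate dehydrogenase subunit, and mlcd-1. Rank 14 (IV, 390342 to 390637, signal 406) lay between ears-2, a glutamyl-tRNA synthetase, and uncp-18, and rank 18 (III, 10461218 to 10461471, signal 391) lay between atx-2, the ataxin-2 gene, and ecps-1. The windows of sre-23 (rank 4) and T02E1.2 (rank 8) also held a top region, but those regions were at the snoRNA genes ZK265.10 and T02E1.9.

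Cytosolic ribosomal protein genes had regions more often than other genes. Among them, 6 of 76 (7.89%) had a region against 1.62% of other protein-coding genes (two-sided Fisher exact test, adjusted p = 0.0166 over 21 gene lists): rpl-3 (signal 255), rpl-20 (160), rpl-15 (145), rpl-35, rps-19 and rps-26, of which the rps-26 region lay at the snoRNA gene F39B2.14. Without regions at small RNA genes the share was 6.58% (exact test, adjusted p = 0.0259). With each region given only to the nearest 5′ end the share was 3.95% and the call ended (exact test, adjusted p = 0.942), since a region in the windows of several genes then counts for 1 of them; with the stronger 246 regions alone it was also 3.95% (adjusted p = 0.192). Genes named as serpentine receptors, a large chemosensory family, had regions less often, 6 of 1171 (0.512% against 1.72%, exact test, adjusted p = 0.0112), among them sre-23, sre-1 and srd-44 (sre-23 at the snoRNA gene ZK265.10 and srd-44 at the tRNA-Arg gene F17A2.t1). The name pattern also took 15 genes of other kinds, srrt-1 with a region among them, and without these the count was 5 of 1156 (0.433%, exact test, adjusted p = 0.00390). In the stronger regions neither list passed (4 of 1171, exact test, adjusted p = 0.619, and 3 of 1156, adjusted p = 0.260), and in a window of 500 bp upstream to 100 bp downstream the fuller list did not (0.342%, adjusted p = 0.0570) while the narrower one did (0.260%, adjusted p = 0.0205).

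No developmental gene list passed the test against other genes after adjustment. Of the 6 Hox genes only ceh-13 itself had one (Fisher exact test, adjusted p = 0.398), and none of the 6 Hox cofactor genes did. Among 64 other homeobox genes, ceh-2 had a region, which lay at a small RNA gene. Regions lay at 1 of 31 Wnt and asymmetry genes (mom-1, needed for Wnt secretion; also at a small RNA gene), 1 of 28 Notch pathway genes (epn-1, the epsin gene), 1 of 41 morphogenesis genes (wve-1, the WAVE gene), 1 of 36 cell cycle genes (lin-35, the retinoblastoma homologue) and 2 of 42 maternal and germline genes (mex-1 and spn-4). In single replicates, ceh-2, epn-1 and mex-1 had no region among the strongest of replicate 2, and spn-4 had none among those of replicate 1. No region was found in the windows of the following lists, in each of which fewer than 1 would be found at the share of all genes: endoderm (13 genes), epidermal (13), muscle (25), pharynx (16) and neuronal (32) fate, major sperm protein (31), intestinal (22) and terminal neuron (29) genes. Histone genes had regions at 4 of 72 (5.56%, Fisher exact test, adjusted p = 0.217), namely the divergent pairs his-67 with his-68 and his-60 with his-59. Histone genes are near-identical copies, so their reads can have been placed at another copy; the list passed in the strongest regions of replicate 2 alone (8.33%, exact test, adjusted p = 0.0124). Heat shock genes had 2 of 22 (hsp-60 and hsp-1, exact test, adjusted p = 0.264), and collagen genes 2 of 156 (col-85 and col-185, both at small RNA genes). None of 175 gene name families passed the adjustment, in which 7 had a raw p under 0.05; the lowest raw p was that of the rpl genes (4 of 47, p = 0.00739, Fisher exact test).

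At the ceh-13 locus 2 regions were found (ceh-13, WBGene00000437, III, 7555660 to 7558041, plus strand). The nearer (7554628 to 7555047, signal 153, rank 191) had its summit at -822 bp from the 5′ end, and the other (7550997 to 7551416, signal 94.0, rank 430) at -4453 bp, in the intergenic stretch towards lin-39. The nearer region was among the strongest 493 of both replicates, and the other among those of replicate 1 only. The lin-39, mab-5, egl-5, nob-1 and php-3 windows held no region. At unc-119, also on the transgene (III, 10902641 to 10908935), no region lay within 20 kb. Reads from the transgene cannot be separated from those of the native ceh-13 locus in these lists.

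**Figure D3:**
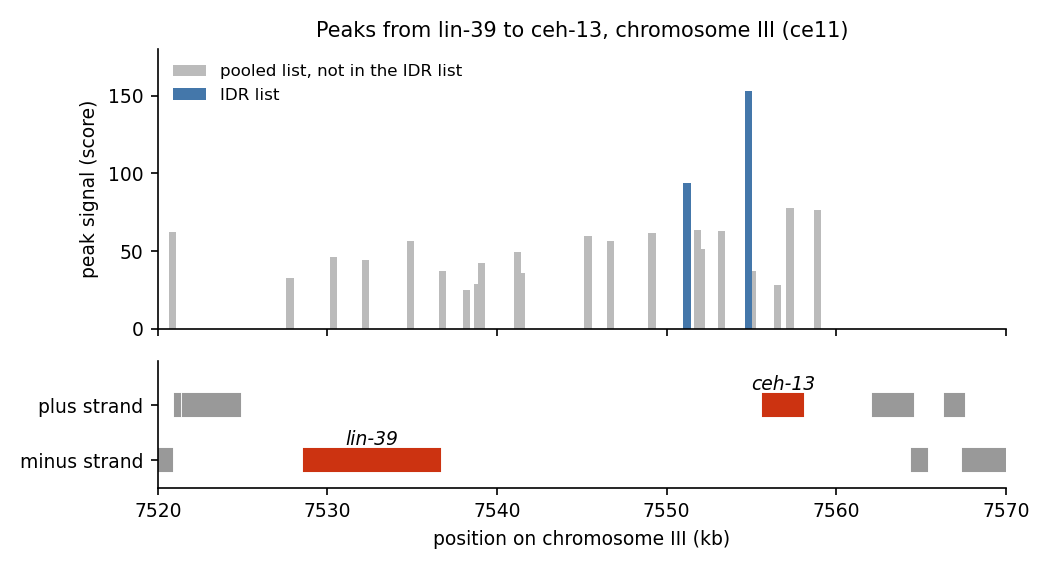
Map of chromosome III from lin-39 to past ceh-13 (x axis, kb, build ce11). Upper panel, signal score of each peak of the pooled list (y axis), with peaks of the IDR list in blue; lower panel, protein-coding genes by strand. The 2 IDR peaks, of signal 153 and 94.0, lie upstream of ceh-13.

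Chromosome X held more regions than its length, and chromosomes IV and V fewer. X had 117 regions (23.7% against 17.7% of the sequence, two-sided exact binomial test, adjusted p = 0.00221), V had 68 (13.8% against 20.9%, adjusted p = 3.76e-04) and IV 63 (12.8% against 17.4%, adjusted p = 0.0105), while I, II and III did not pass. The call for IV ended in the strongest regions of replicate 2 alone and in the stronger 246 regions. The X excess was found at small RNA genes, where 83 of 263 regions were on X (31.6%, exact test, adjusted p = 2.49e-07). Away from them X had 34 of 230 (14.8%, exact test, adjusted p = 0.359), IV had 31 (13.5%, adjusted p = 0.236) and V had 37 (16.1%, adjusted p = 0.224), so none of these passed, and chromosome III had 48 (20.9% against 13.7%, adjusted p = 0.0171). Of all tRNA genes 45.1% are on X, and the share with a region on X did not differ detectably from that on autosomes (35.1% and 34.8%, two-sided Fisher exact test, adjusted p = 0.932).

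Sequences of the Hox type were not more frequent under the summits than in control windows. The composite site of Hox and PBC proteins (TGATNNAT) was in 7.51% of the 493 windows of 100 bp to each side of the summit, lower than the 11.3% of control windows matched on chromosome, promoter state and GC content (two-sided Fisher exact test, adjusted p = 0.0198 over 10 motifs). In the stronger 246 regions that difference did not pass (odds ratio 0.899, exact test, adjusted p = 0.749). The homeodomain site TAATTR was in 11.2% against 13.0% (exact test, adjusted p = 0.303). It was lower than in flanking windows (odds ratio 0.427, exact test, adjusted p = 2.29e-07) and than in controls without GC matching (odds ratio 0.408, adjusted p = 7.70e-11). Neither of these 2 sets was matched on GC content, which was 45.4% in the summit windows against 35.4% of the genome. Base composition can therefore give such differences, for this site and for the GC box below. The scrambled composite control stood at 6.69% in both. Higher than in controls were the GC box GGGCGG (15.8% against 7.63%, odds ratio 2.28, exact test, adjusted p = 1.06e-07; odds ratio 5.43 against flanking windows and also without GC matching), the forkhead site TGTTTRC (10.5% against 5.09%, adjusted p = 2.18e-05) and the GAGA repeat (22.7% against 15.1%, adjusted p = 7.90e-05); the GAGA call ended in windows of 50 bp to each side (odds ratio 1.25, adjusted p = 0.227), and the forkhead call ended without the regions at small RNA genes (odds ratio 1.73, adjusted p = 0.0713). The POP-1/TCF site CTTTGW was lower (14% against 21.2%, exact test, adjusted p = 2.73e-04), with an odds ratio of 0.606; in the stronger regions, which are fewer, it was 0.702 and did not pass (adjusted p = 0.138). Away from small RNA genes the odds ratio of this site was 0.439 (exact test, adjusted p = 3.20e-04). At small RNA genes it was 0.760 and did not pass (exact test, adjusted p = 0.225).

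Of all 6-mers, counted with their reverse complements, 357 were more frequent and 335 less frequent than in controls after adjustment. Here too the controls were not matched on exons, and whether this adds to both counts was not tested. At small RNA genes the leading 6-mer was CGAACC, in 58.2% of windows against 6.08% (Fisher exact test, adjusted p = 1.19e-89). Away from them it was CCGCAC, in 23.9% against 4.61% (exact test, adjusted p = 2.74e-17), followed by CGCACA, in 25.22% against 5.26%. The reverse complement of CGAACC, GGTTCG, overlaps GTTCRANNC, the tRNA gene element called the B box and described below. Of the 263 regions at small RNA genes, 192 lay at tRNA genes. The lead of CGAACC can therefore follow from the sequence of those genes and is no separate evidence on binding.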

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

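Alternatives that left out the regions at small RNA genes from the chromosome and motif tests, those on the share at small RNA genes, and the serpentine list without other genes, were chosen after seeing the data. That share (53.3%) stayed far above the genome under each of its alternatives, at 45.6% to 53.5% in single replicates and 69.1% in the stronger 246 regions, and the promoter share stayed above its background in each of its alternatives (34.1% to 71.3%). Single replicates gave 1 to 2 enriched gene lists. In the stronger regions, 146 genes had a region in their window, 0 lists were enriched, 0 lists and 0 motifs were depleted, and 1 region lay at the transgene loci, with fewer regions tested. The window of 500 bp upstream to 100 bp downstream, narrower by construction, gave 218 genes and 0 depleted lists, and the nearest 5′ end alone gave 0 enriched lists. Motifs lower than in controls numbered 4 in windows of 50 bp to each side, 4 against flanking windows and 5 without GC matching. The last 2 sets of controls were not matched on GC content, so base composition can add to these counts, and the cause was not tested. Without regions at small RNA genes 1 chromosome differed from its length, and the X share turned to 14.8%, below its length. Replicate overlap was 57.8% with reciprocal overlap, 78.9% with N halved and 50.8% with N doubled, and the rank correlation was 0.328 on the q-value column. In that column 383 peaks of replicate 1 and 221 of replicate 2 were tied at the highest value, and whether ties account for the lower correlation was not tested. Of all 329 genes with a region, 267 kept it without replicate 2 and 223 without replicate 1; of the 29 named by rule, 28 (not spn-4) and 26 (not ceh-2, epn-1 or mex-1) did, with 16 in the narrower window and 17 under the nearest 5′ end. The pooled list gave the same regions, so it tests nothing. No paired analysis was possible because there is 1 group. The unknown depth limits any statement on regions that were not called.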

Other observations

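The tests on other RNA polymerase III genes, on X background peaks, on the transgene, on B boxes away from small RNA genes and on multi-copy tRNA genes were chosen after related results had been seen, and the RNA genes named in this part were chosen after their values were seen. Some regions away from annotated tRNA, snoRNA and snRNA genes lay at other small structural RNA genes. Rank 52 (II, 7200203 to 7200352, signal 284) lay at mrpr-1, the RNA of RNase MRP, rank 61 (I, 13463937 to 13464078, signal 272) at rpr-1, the RNA of RNase P, and rank 96 (III, 5031316 to 5031937, signal 231) at srpr-2.2, a signal recognition particle RNA gene. Of the 8 genes named for the RNAs of RNase P, RNase MRP, the signal recognition particle and the Y RNA, 5 had a region, and srpr-1.1, srpr-3 and yrn-1 had none, against 241 of 7756 other noncoding RNA genes (3.11%; two-sided Fisher exact test, p = 1.59e-06). That set was assembled after 3 of its members had been seen with a region, so this p is not independent evidence. Rank 10 (IV, 11025861 to 11026396, signal 463) lay at mir-51 and rank 54 (IV, 14033937 to 14034196, signal 282) at mir-52, although only 3 of 261 microRNA genes (1.15%) had a region. Of 15363 piRNA genes 17 (0.111%) had a region. tRNA genes, like the RNase P, RNase MRP and signal recognition particle RNA genes, are transcribed by RNA polymerase III as a rule.

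A hypothesis from this is that the strongest signal follows RNA polymerase III promoters of the tRNA type. Against a wider form of it, none of the 16 annotated 5S rRNA genes, which this polymerase also transcribes, had a region, and the region of rank 1, at K12H4.5, lay away from small RNA genes. The 5S result is weak evidence, since it rests on 16 genes and the lists do not show how reads shared between repeated genes were placed. The B box, an internal element of tRNA genes bound by TFIIIC, has a consensus GTTCRANNC, which was in 80.2% of the 263 windows at small RNA genes against 5.82% of controls; in tRNA genes this follows from the gene's own sequence. snoRNA genes give a test that does not, because their B box, where present, lies upstream. Of 37 snoRNA genes with the consensus in the 150 bp upstream, 26 (70.3%, 95% interval 54.2 to 82.5) had a region, against 36 of 307 without it (11.7%, 95% interval 8.59 to 15.8; two-sided Fisher exact test, p = 5.88e-14; 2 genes near tRNA genes left out). This is consistent with the hypothesis, and it was found and tested on the same data. Among the 230 regions away from small RNA genes the consensus was in 6.96% (95% interval 4.33 to 11) against 4.83% of controls (two-sided Fisher exact test, p = 0.155), so whether a few of them are unannotated sites of this kind cannot be told apart from background. The 16 regions with it were those of rank 10, at mir-51, and of ranks 36, 56, 99 and 113, with the others from rank 155 to 481. Whether stronger regions hold it more often was not tested.

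The excess at small RNA genes has several possible technical sources. Reads shared between identical genes as the whole source are argued against by the 140 single-copy tRNA genes, of which 22.1% had a region (95% interval 16.1 to 29.7) against 0.560% of random stretches of the same length. Single-copy means here that the exact gene sequence occurs once in the genome. Reads shared with a near-identical gene, or a region of a multi-copy tRNA gene within 500 bp, were not excluded. tRNA-like sequence of any kind as the source is argued against by pseudogenes at 1.44%. How much of the tRNA promoter sequence, such as the B box, the pseudogenes keep was not examined, so the sequence of intact tRNA genes stays open. A single deviating replicate is argued against by an enrichment over the genome of 41.8-fold in the lower replicate (39.8-fold with the genome weighted by chromosome). Weak background peaks that follow the same genes are argued against by 1.13% among pooled peaks beyond rank 5000. Those peaks are weak, so their share does not bear on background strong enough to give peaks of high rank. Multi-copy tRNA genes had regions more often than single-copy ones (38.8%, two-sided Fisher exact test, adjusted p = 3.53e-04), without a rise beyond that (43.4% with 2 to 5 copies, 38% with 6 to 10 and 37.7% with over 10), and shared reads or higher activity of those genes cannot be told apart, since the lists do not show how repeated reads were placed and reads spread evenly over the copies need give no rise. Binding directed by the Hox-PBC composite site was not seen, at 8.75% of windows against 10.7% of controls, but the upper limit of 12.8% includes the controls, and signal from accessible, heavily transcribed genes in any anti-GFP experiment was not tested, because no other ChIP was analysed here.

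The excess of chromosome X may come from where tRNA genes lie. Away from small RNA genes the X share was 14.8%, not above its 17.7% of the sequence. A general excess of called peaks on X is argued against by its 15.7% of the weaker pooled peaks. No biological explanation was tested, since the design has 1 group.

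The regions at ceh-13 could reflect binding of the protein at its own gene or the presence of the gene on the transgene. Extra copies that raise the background over the whole insert could not be excluded with these lists. No region lay within 20 kb of unc-119, but a region is a strong peak, so its absence does not measure background. The number of weaker pooled peaks within 20 kb of ceh-13, 21, was at percentile 81.9 of windows of that span on chromosome III. It was below the 95th percentile of 25, the limit set for this test, and above the median of 16. Within 5 kb the percentile was 82.4 for ceh-13 and 63.7 for unc-119, whose percentile within 20 kb was 90.0. Within 20 kb all pooled peaks per 100 kb, the regions themselves included, were 54.3 at ceh-13 and 54 at unc-119, against 29.9 in the genome. Within 5 kb they were 72.7 and 43. The weaker pooled peaks within 5 kb of ceh-13 had signals of 28.2 to 77.8, against a median of 32.1 in the pooled list. A rise of background at these loci therefore stays open. The ceh-13 regions rank 191 and 430 among the 493, and binding at the native locus was not tested apart from the transgene.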
